A study of Mus musculus with 20 samples.

How the data were processed

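Poly(A) RNA was measured by single-end sequencing in 20 libraries from male C57BL/6N mice on chow: 10 from the pituitary and 10 from inguinal white adipose tissue (iWAT, the subcutaneous fat depot of the groin). In each tissue 5 libraries are labelled wild type (WT) and 5 are labelled Klf14 knockout (KO). The labels give reads of 100 nucleotides and about 46 M (mega) reads per sample. The mouse numbers in the sample titles were used as replicate names. Genotype and age are the same for each number in both tissues, but no label says that a number stands for one animal. No label says in words that the libraries of a group come from separate animals either, so the p-values measure the spread between these libraries.

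The deposited files hold whole-number read counts per gene, made by the authors with featureCounts and not normalized, per the file headers. The submitters' processing notes name STAR 2.4.0 and featureCounts 1.4.4 and the builds mm10 and GRCm38. Per the file headers, reads were counted over the exons of an mm10 gene annotation from UCSC, only primary alignments were used, and a read that overlapped several genes was counted for each of them. The headers give no strand option, so reads from overlapping genes on opposite strands cannot be told apart. Of the 24062 genes, 3147 share exon bases with another gene.

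Total counts ranged from 13.6 to 17.6 M in the pituitary libraries and from 14.8 to 18.7 M in the iWAT libraries. At the median depth the counting error of a gene at 1 CPM (counts per mega-count of the library) is a coefficient of variation of 0.254 in the pituitary and 0.248 in iWAT. It equals the spread between mice at 6.31 CPM in the pituitary and at 0.649 CPM in iWAT, so below these levels counting error sets the precision. Within each group every pair of libraries differed by more than sampling noise. The smallest reduced chi-square between 2 libraries of a group was 4.51, so all 20 were kept as separate samples.

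Each tissue was fitted alone with edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, robust quasi-likelihood fit and test, Benjamini-Hochberg adjustment, adjusted p threshold 0.05). No covariate was used. Fold changes are labelled KO over labelled WT on the log2 scale, with a standard error taken as the fold change over the square root of the F statistic. Whether the KO effect differed between tissues was tested as a contrast of the 4 groups in 1 fit over all 20 libraries. CPM values use TMM-scaled library sizes unless stated otherwise and are given as mean ± SD over 5 libraries. The Klf14 level was also compared by an exact two-sided permutation test over the 252 assignments, on CPM from library sizes without TMM scaling. The smallest p this test can give is 0.00794.

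There were 37 gene lists covering pituitary and adipose cell types, other cell types a dissection can hold, metabolic and stress pathways, reported KLF14 targets and the Klf14 neighbourhood. They were tested with camera in limma 3.58.1 (preset correlation 0.01) on log2 CPM with a prior count of 2, where at least 5 members were tested. Camera with an estimated correlation and fry were the alternatives. List scores are the mean log2 CPM of the tested members. Of the list genes, 3 had no matching symbol and 1 was matched by an older symbol. Genes within 5 Mb of Klf14 were summarized by their median, and calls per chromosome were compared by Fisher's exact test.

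Genes are named by a rule: Klf14, the 12 higher and 12 lower genes with the smallest p among those past the threshold, list members past the threshold, the list members with the highest CPM as examples of level, and tested genes within 1 Mb of Klf14. Not every gene that the rule names is given in the text or drawn. Where few genes passed, the 12 genes with the smallest unadjusted p are given as values only. A gene named outside this rule was chosen after its values were seen, which holds for the list members named because they passed over their list alone and for the genes named because an alternative called them. The design, the lists, the naming rule and the alternatives, except those named as added, were fixed before the data were examined.

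The alternatives were RLE scaling, leaving out the 20 most abundant genes, no filter, a filter of more than 1 CPM in at least 5 libraries, DESeq2 1.42.0, limma voom with quality weights, age as a covariate, mice of 21 weeks only, an adjusted p threshold of 0.1, leaving out each mouse, 1 fit over all 20 libraries, scores of other cell types as covariates, and the mouse number as a block. Surrogate variables from sva 3.50.0, 3 cell type scores together in iWAT and gene lists without each mouse in turn were added after seeing the data. The fits were tested on simulated counts drawn from the real means and dispersions, with 200 genes changed. In simulated pituitary data over 16291 genes, edgeR called 65.7% of genes changed 1.5-fold and 86.6% of genes changed 2-fold, and 10 of its 174 calls were unchanged genes. DESeq2 made 198 calls there, 27 of them unchanged genes. In simulated iWAT data over 15954 genes, edgeR called 10.4% of genes changed 1.5-fold, 52.2% at 2-fold and 77.3% at 4-fold. DESeq2 called 38.8% at 1.5-fold and 83.6% at 2-fold there, and 46 of its 186 calls were unchanged genes. In the simulated contrast between tissues over 17614 genes, edgeR called 19.4% at 1.5-fold, 50.7% at 2-fold and 71.2% at 4-fold. That simulation gave both tissues the same spread for each gene, and the real contrast also used 1 estimate for both. The real tissues differed, with a biological coefficient of variation of 0.101 in the pituitary and 0.307 in iWAT, so these shares may not hold for the real contrast.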

Results

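Gene expression was profiled in the pituitary and in iWAT of male mice described as germline knockouts of Klf14, a Krüppel-like zinc finger transcription factor, and of mice described as wild type. Each tissue gave 5 libraries labelled WT and 5 labelled KO. The pituitary libraries held 13.6 to 17.6 M counts and the iWAT libraries 14.8 to 18.7 M. Marker genes separated the tissues: Gh, which encodes growth hormone, lay between 72134 and 120315 CPM in the pituitary libraries, with a median of 0.339 CPM in iWAT, and Adipoq, which encodes adiponectin, lay between 646 and 2158 CPM in iWAT, with at most 0.065 CPM in the pituitary. The mice labelled KO were on average 20.6 weeks old and those labelled WT 19.6 weeks, and 4 of 5 KO against 2 of 5 WT mice were 21 weeks old.

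Klf14 itself was measured first, because the targeted gene checks the genotype labels. In the pituitary its counts were higher, not lower, in the libraries labelled KO: 33.4 ± 3.03 CPM (SD, n = 5) against 16.6 ± 1.85 CPM (SD, n = 5) in those labelled WT, a 2.01-fold difference. Raw counts were 417 to 679 in the labelled KO and 196 to 304 in the labelled WT libraries, and all 25 pairs of a labelled KO and a labelled WT library had the KO higher. The difference passed edgeR's quasi-likelihood test (log2 fold change 1.004, SE 0.086, adjusted p = 7.645e-05) and the exact permutation test (two-sided p = 0.00794, the smallest it can give). In iWAT Klf14 was near the limit of detection, with 1.51 ± 0.787 CPM in labelled KO and 0.892 ± 1.21 CPM in labelled WT libraries (SD, n = 5 each, exact permutation p = 0.349), and with mice of 21 weeks only its log2 fold change there was -0.10.

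The counts cover 1 exon of Klf14 on chromosome 6, from 30956021 to 30958990 on the minus strand (mm10). In the GENCODE annotation of GRCm38 the coding sequence runs from 30957723 to 30958697, which is 975 bases or 32.8% of the length of the counted exon, and the rest of the transcript is untranslated. No other annotated gene overlaps it. Which part of the gene was deleted is not given in the sources used here, and counts summed over the whole exon cannot show whether the coding part is missing. The counts therefore cannot show that the genotype labels are right, nor tell them from labels exchanged in all libraries. All directions below are those of libraries labelled KO against libraries labelled WT.

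**Figure D1:**
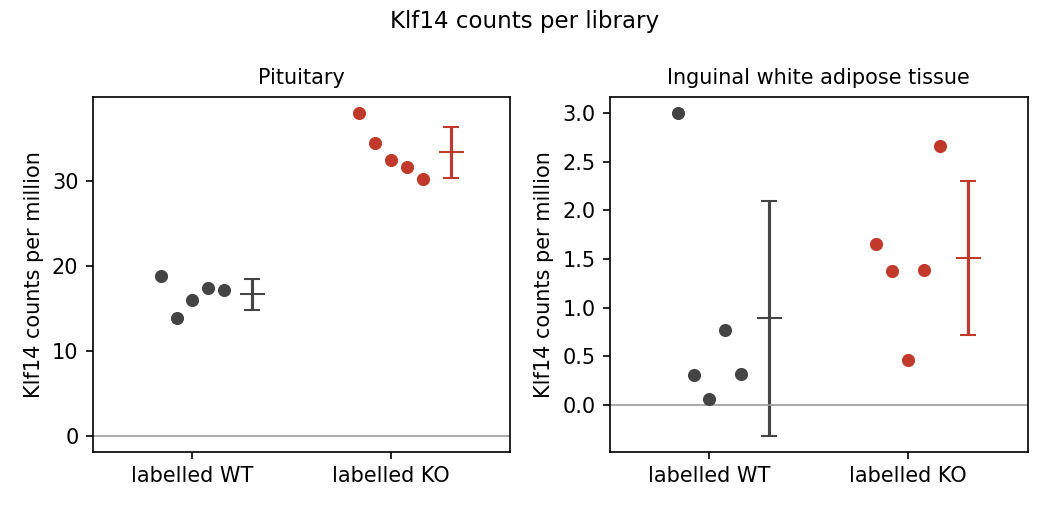
Klf14 CPM in each library (points) by labelled genotype, with the mean and SD of 5 libraries beside them, in the pituitary (left) and iWAT (right); the vertical scales differ. In the pituitary the labelled KO libraries lie between 30.2 and 38.0 CPM and the labelled WT libraries between 13.9 and 18.8 CPM.

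In the pituitary, 90 genes differed between the labelled genotypes, 68 higher and 22 lower in labelled KO. Besides Klf14, the higher genes with the smallest p were led by Cldn7, which encodes the tight junction protein claudin-7 (13.6 ± 0.942 against 6.58 ± 0.387 CPM, log2 fold change 1.04), and Rcn1, which encodes a calcium-binding protein of the endoplasmic reticulum (111.3 ± 6.92 against 74.1 ± 4.69 CPM, log2 fold change 0.59; SD, n = 5 each). Galnt5, an enzyme that starts O-linked glycosylation, rose 2.76-fold, the most among the named genes, from a low level of 0.945 ± 0.141 CPM. Tgfa, a ligand of the epidermal growth factor receptor, rose by 0.80 on the log2 scale and Pign, an enzyme of glycosylphosphatidylinositol anchor synthesis, by 0.45. Among the lower genes, Klk1, which encodes tissue kallikrein, fell by 1.32 on the log2 scale (SE 0.22, edgeR adjusted p = 0.0528 without WT replicate 49) and Vwde fell by 1.28 (SE 0.17).

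Further genes were named by the rule. Efs, Ablim3, Rimklb, Plekhn1, Atat1 (the tubulin acetyltransferase) and Med12l were higher in labelled KO, with log2 fold changes from 0.34 for Med12l to 0.78 for Efs. Vwc2, Loxhd1, Megf10, Sfmbt2, Zfyve28, Sprn, Sytl1, Tubb3 (a neuronal beta-tubulin) and Lrrc9 were lower, from -0.98 for Vwc2 to -0.39 for Lrrc9. Most calls were small: 58 of the 90 differed by less than 1.5-fold and 8 by 2-fold or more. In all 90 the 5 labelled KO libraries lay on one side of the 5 labelled WT libraries, as did 2.83% of all tested genes, against 0.794% by chance. Med12l, Sprn and Prmt2 are among 10 called genes that share exon bases with another gene, so their counts are uncertain.

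The test covered 16389 genes (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), of which 1792 had an unadjusted p under 0.05 against 819 expected by chance. With age as a covariate 44 genes passed, with mice of 21 weeks only (4 KO, 2 WT) 5 passed (Megf10, Rcn1, Tgfa, Col24a1 and Tenm1), with all 20 libraries in 1 fit 1 gene (Pign) passed, with DESeq2 288 passed, and without KO replicate 32, WT replicate 49 or WT replicate 56 the count was 55, 50 or 51.

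**Figure D2:**
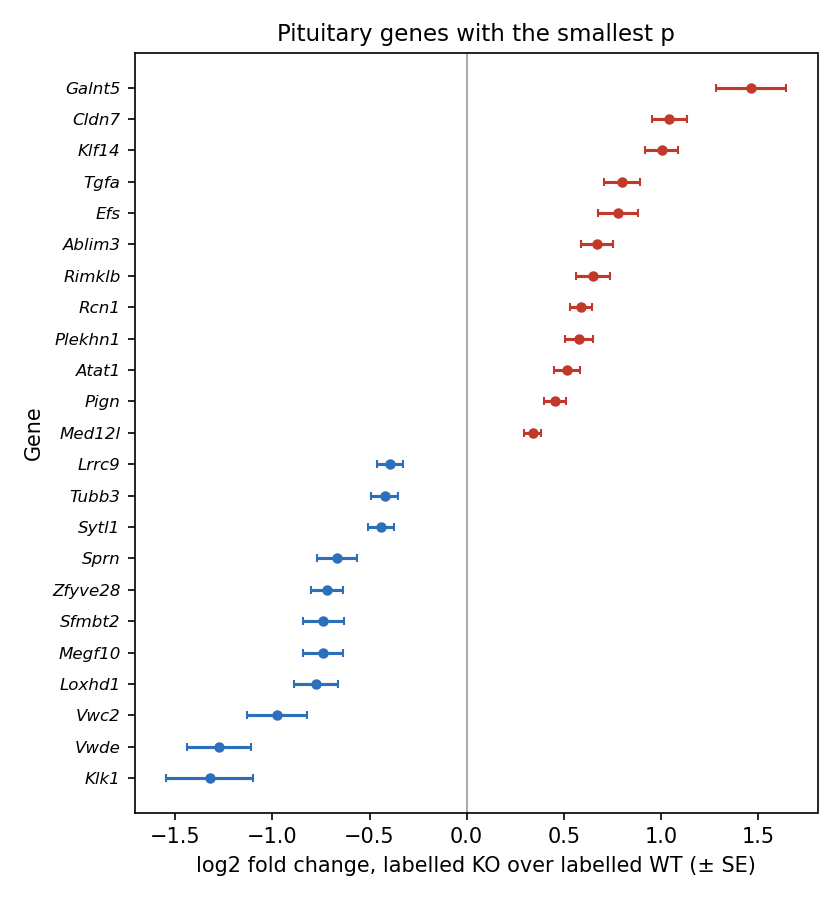
Log2 fold change of labelled KO over labelled WT with its standard error (horizontal axis) for 12 higher and 11 lower pituitary genes among those with the smallest p, 5 libraries per group. Values run from -1.32 for Klk1 to 1.47 for Galnt5.

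Genes that define the hormone-producing cells of the pituitary mostly did not pass. None of the somatotroph genes passed, over all genes or adjusted over the list alone, and Gh was 99557 ± 17595 CPM in labelled KO against 96324 ± 17654 CPM in labelled WT (SD, n = 5 each). In the gonadotroph list 0 of 8 members passed over all genes and 2 passed adjusted over the list alone: Cga, the common glycoprotein hormone subunit (2304 ± 142 against 2807 ± 255 CPM, edgeR adjusted p = 0.0558 over all genes), and Lhb, the luteinizing hormone subunit (log2 fold change -0.23). The camera adjusted p of that list was 0.158 (adjusted p = 0.838 with an estimated correlation). In the corticotroph and melanotroph list Nr3c1, the glucocorticoid receptor, rose by 0.24 on the log2 scale (edgeR adjusted p = 0.0415), and 2 of 10 members passed adjusted over the list alone, Nr3c1 and Oacyl, whose log2 fold change was 0.61 (camera adjusted p = 0.0773; adjusted p = 0.838 with an estimated correlation). The call of Nr3c1 was lost in 8 of the 10 fits that left out a mouse. Pomc, the precursor of adrenocorticotropin, was 10035 ± 2705 against 7306 ± 2109 CPM and did not pass (edgeR adjusted p = 0.565).

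All 14 chaperones of the heat shock and protein folding list had positive log2 fold changes, with a median of 0.15. None passed over all genes, and Hspa5, Pdia4 and Hsp90b1, chaperones of the endoplasmic reticulum, passed adjusted over the list alone (3 of 14). It was the only one of 25 lists to pass camera in the pituitary (adjusted p = 0.00392; adjusted p = 0.838 with an estimated correlation). It passed in 9 of the 10 fits that left out a mouse (camera adjusted p = 0.0622 without KO replicate 66), and with age as a covariate its camera adjusted p was 0.354, in a range from 7.57e-06 to 0.838 over the alternatives. In the KLF and SP family, Klf16 rose by 0.62 on the log2 scale (edgeR adjusted p = 0.0138) and was the 1 of 19 members to pass over all genes and adjusted over the list alone (camera adjusted p = 0.755; adjusted p = 0.838 with an estimated correlation). Among orthologues of genes that the human KLF14 locus regulates in trans, the arginine methyltransferase gene Prmt2 was the 1 of 11 to pass, over all genes and adjusted over the list alone, with a log2 fold change of 0.49 (camera adjusted p = 0.776; adjusted p = 0.838 with an estimated correlation). Its call was also lost in 8 of the 10 fits that left out a mouse.

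Adjusted over the list alone, Esr1, the estrogen receptor gene, passed in the lactotroph list (1 of 5) and with Nr3c1 in the list of hormone receptors and feedback genes (2 of 17), and Cga in the thyrotroph list (1 of 5). The camera adjusted p of these lists was 0.921, 0.489 and 0.755 (adjusted p = 0.922, 0.838 and 0.838 with an estimated correlation). In 15 of the 25 lists, namely the somatotroph, macrophage, cell cycle, circadian clock, cholesterol synthesis, interferon, immediate early gene, blood, oxidative phosphorylation, secretory granule, posterior lobe, neuron, endothelial, folliculostellate and other reported KLF14 target lists, no member passed adjusted over the list alone. Which lists passed camera depended on the mice and on age. With age as a covariate 3 lists passed, macrophage markers (adjusted p = 0.00269) and interferon response (0.0309) higher and immediate early genes (0.0343) lower. The count of lists was 0 without KO replicate 66, 2 without WT replicate 33, 4 without KO replicate 35 or WT replicate 49, and 3 without KO replicates 31, 32 or 50 or WT replicates 48 or 56. Immediate early genes passed as lower in 5 and the corticotroph and melanotroph list as higher in 4 of these 10 fits. Fry for a change in either direction passed in 5 lists, those of the Klf14 neighbourhood, the KLF and SP family, corticotrophs and melanotrophs, substrain genes, and receptors, and fry for a shift one way passed in 0. The median and the camera direction differed in sign for the lactotroph, thyrotroph, somatotroph and trans-network lists, and the mean and the camera direction for the KLF and SP, neighbourhood and folliculostellate lists.

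Markers of other cell types set 2 labelled KO pituitary libraries apart. In KO replicate 66 the posterior lobe score was 4.29 against at most 3.54 in the other 9 libraries, and its blood marker score of 7.05 was second to the 7.24 of KO replicate 50. In KO replicate 50 the macrophage score was also the highest of the 10, and that library stood apart on the first dimension of a multidimensional scaling plot (1.35 against -0.35 to 0.067 in the others). Of the macrophage markers 12 of 13 had positive log2 fold changes, and 0 passed over all genes or adjusted over the list alone (camera adjusted p = 0.147; adjusted p = 0.838 with an estimated correlation). The camera adjusted p of that list was 0.00269 with age as a covariate and 0.953 without KO replicate 50. Without that library 112 genes passed, 75 of them among the 90, and the cell cycle list passed camera as lower in labelled KO (adjusted p = 0.00431, against 0.395 with all mice and from 0.339 to 0.898 under the other alternatives). Nnt, a gene that is partly deleted in the related substrain C57BL/6J, was at 130.5 ± 6.36 CPM in labelled KO and 115.9 ± 3.11 CPM in labelled WT. In the list of substrain genes 3 of 5 members, Nnt, Crb1 and Wdfy1, passed adjusted over the list alone and 0 over all genes (camera adjusted p = 0.429; adjusted p = 0.838 with an estimated correlation).

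Genes near Klf14 were examined because a targeted allele can affect its neighbours. Mest and Copg2, imprinted-region neighbours of Klf14, did not pass in the pituitary (edgeR log2 fold changes -0.15 and -0.12). The median log2 fold change of the 61 other genes tested within 5 Mb was 0.013 in the pituitary. In iWAT 0 of 61 such genes passed with edgeR, where 0 of all genes passed. The list of this neighbourhood did not pass camera in the pituitary (adjusted p = 0.429; adjusted p = 0.838 with an estimated correlation).

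In iWAT no gene passed the test between the labelled genotypes. Adipocyte genes were close in both groups: Adipoq was 1323 ± 547 CPM in labelled KO against 1277 ± 446 CPM in labelled WT, Fabp4 was 6108 ± 2312 against 5349 ± 1945 CPM, and the fatty acid synthase gene Fasn was 1463 ± 1426 against 1499 ± 501 CPM (SD, n = 5 each). Of the lipogenesis, lipolysis, thermogenic, insulin signalling and adipokine lists, no member passed over all genes or adjusted over the list alone, and none passed camera. With age as a covariate the lipogenesis (camera adjusted p = 0.0495) and lipolysis (0.0355) lists passed as higher in labelled KO, and without KO replicate 50 both passed as lower (0.0108 and 0.00133), as did the thermogenic list (4.655e-06). The 12 genes with the smallest unadjusted p included Igfbp2 (7.84 ± 2.95 against 2.56 ± 1.81 CPM), Garnl3 (7.21 ± 0.929 against 9.88 ± 0.934 CPM) and the acute-phase gene Saa1, whose labelled KO mean of 33.4 CPM came from KO replicate 50 at 152.6 CPM.

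The iWAT libraries differed in the levels of marker genes of other tissues. The lymph node score, from B and T cell genes, was 1.23 in KO replicate 50 against 5.92 in the next lowest labelled KO library, and the skeletal muscle score spanned 4.94 log2 units over the 10 libraries. The biological coefficient of variation was 0.307 in iWAT and 0.101 in the pituitary. Of 27 lists 5 passed camera in iWAT: skeletal muscle higher in labelled KO (adjusted p = 1.106e-04) and heat shock and protein folding higher (adjusted p = 0.0216), and lymph node (adjusted p = 0.00114), interferon response (adjusted p = 0.00176) and macrophage markers (adjusted p = 0.0184) lower. Fry for a shift one way gave 0 lists in either tissue. In each of the 5, 0 members passed over all genes or adjusted over the list alone, and each had an adjusted p = 0.767 with an estimated correlation. Without KO replicate 50, 11 lists passed, 6 of them in the direction opposite to that with all mice, and the lymph node list was higher, not lower, in labelled KO (camera adjusted p = 0.00549) while the heat shock list did not pass (0.268). With age as a covariate the skeletal muscle list turned to lower and did not pass (camera adjusted p = 0.913), nor did the heat shock (0.293) and macrophage lists (0.333).

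The other 22 lists did not pass camera in iWAT with all mice, and in all 27 no member passed adjusted over the list alone. Oxidative phosphorylation passed as higher with age as a covariate (adjusted p = 3.756e-04) and as lower without KO replicate 50 (2.954e-07). Without that replicate the endothelial (4.474e-04) and blood (0.00135) lists also passed as lower and cell cycle (0.00150) as higher. The count of lists was 9 without KO replicate 31 or WT replicate 33, 3 without KO replicate 35 or 66, and 1 without WT replicate 48. The median and the camera direction differed in sign for the extracellular matrix list (median -0.13, camera higher), and likewise for the preadipocyte and fibroblast, cell cycle and endothelial lists. For the lists of other reported KLF14 targets and of endothelial markers the mean and the median differed in sign.

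The iWAT test covered 16105 genes with edgeR, and 89 had an unadjusted p under 0.05 against 805 expected by chance. DESeq2 and limma voom also called 0 genes, with 127 and 247 at an unadjusted p under 0.05.

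**Figure D3:**
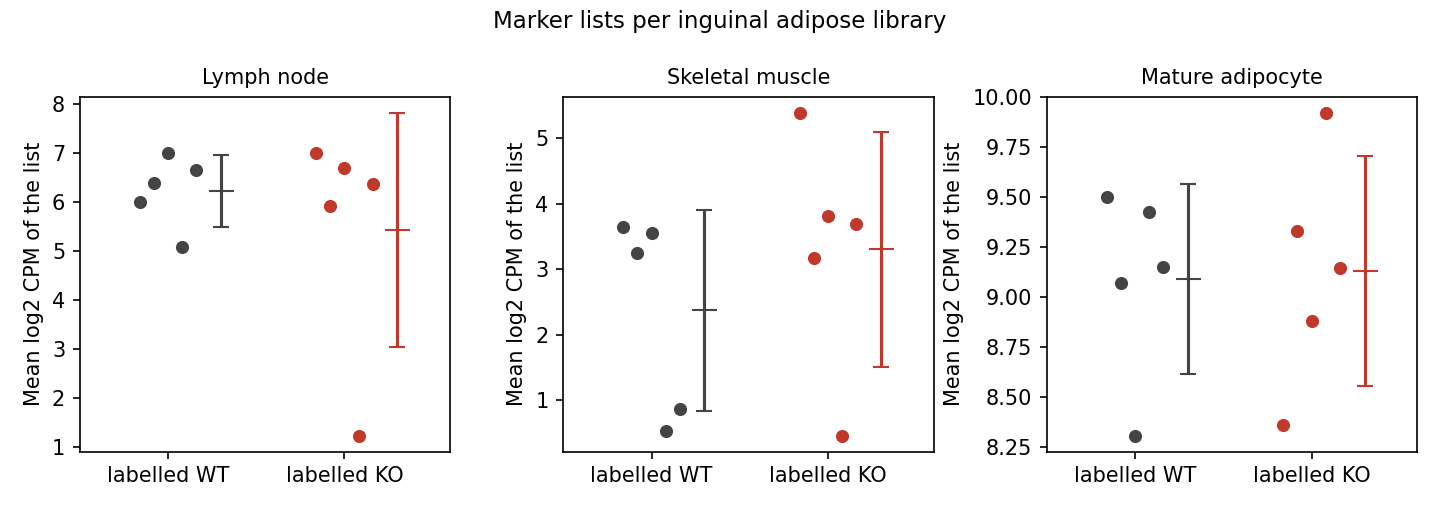
Mean log2 CPM of 3 marker lists in each iWAT library (points) by labelled genotype, with the mean and SD of 5 libraries beside them; the vertical scales differ and do not start at 0. The lymph node score of one labelled KO library lies at 1.23.

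The comparison of the tissues asked whether the labelled KO effect differed between them. Pign, higher in labelled KO pituitary, had the smallest p of the contrast (log2 difference -0.42, iWAT minus pituitary, edgeR adjusted p = 0.750). No gene of 17731 passed, and 427 had an unadjusted p under 0.05. With DESeq2 Pign passed and with age as a covariate Mmp8 passed, 1 gene each, and limma voom called 0 (538 at an unadjusted p under 0.05). Of the 90 pituitary calls 10 had an adjusted p under 0.05 in the contrast when adjusted over these 90 alone, among them Megf10 and Klf16. The 90 were chosen on the pituitary difference that enters the contrast, so this is not independent evidence. Of 74 pituitary calls that were also tested in iWAT, 43 had the same sign there, and their iWAT log2 fold changes, signed by the pituitary direction, had a median of 0.034 (SD 0.31). With 0 calls in iWAT no overlap of calls could be tested.

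Across the 14854 genes tested in both tissues, the log2 fold changes had a Pearson correlation of 0.108, a Spearman correlation of 0.068 and a covariance of 0.00409. Genes are not independent replicates. In 100 splits of the same mice into 5 and 5, the real one included, 39 gave a Pearson correlation as high, and the median covariance of the others was 0.00402.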

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

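The tests of wrong and of exchanged labels, of scaling, of depth, of posterior lobe share, of mice of equal age and of the splits in iWAT and between tissues were chosen only after the result was seen. The tests of age, of lymph node share, of simulated changes and of the pituitary splits were written before their own values were seen. They were written after the main fits and their alternatives had been run on the real data, so their limits were not set blind to those results.

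Klf14 counts were 2.01-fold higher in pituitary libraries labelled KO. Wrong labels on some pituitary libraries are argued against by the 25 of 25 pairs with the labelled KO higher. A scaling artefact is argued against by the lowest log2 difference of 0.95 over the alternatives. In iWAT, where Klf14 was near detection, 19 of 25 pairs had the labelled KO higher, so the labels there could not be checked this way. An exchange of the genotype labels in all libraries cannot be told apart from correct labels. The lowest count in a labelled WT library was 196, so neither group lacks the whole exon, and a deletion of part of it could leave counts in either. A higher level of a transcript from the targeted allele stays open as a biological explanation and was not tested.

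The 90 pituitary calls exceed what other groupings of the same libraries gave. Of 100 splits drawn from the 126 distinct ones, 1 gave as many calls, the real one, and the highest other split gave 11. By genes with an unadjusted p under 0.05 (1792 in the real split), 4 of the 100 gave as many, the real one included. The highest other split gave 2052 such genes. The call counts argue against chance as the whole source, but 100 splits cannot exclude it. A linear trend with age was tested between the 2 older and the 3 younger WT mice. The called genes moved by a median of 0.0085 log2 units (SD 0.073) in the KO direction, scaled to the age gap of the groups. This lay below their median KO difference of 0.51 by more than the SD. Of 10 choices of the older mice, 2 gave a median as high. The genes were chosen partly for a small spread within these WT libraries, so the small median cannot decide on a trend with age. With the posterior lobe score as a covariate 76 of the 90 stayed called, which argues against a posterior lobe share as the whole source. Among mice of 21 weeks the log2 differences of the 90 genes were a median of 0.999 times (SD 0.168) those among all mice. In these 6 libraries 4 of the 90 stayed called, with a median SE of 0.109 against 0.084. These values argue only weakly against age of any shape as the whole source, because the 6 libraries were among those that chose the genes. An effect of the labelled genotype stays open.

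In iWAT edgeR called 0 genes (89 at an unadjusted p under 0.05, with 127 by DESeq2 and 247 by limma voom, which also called 0), and lower depth is argued against by a median of 16.3 M counts, above the 15.4 M of the pituitary. Uneven lymph node share is argued against as the whole source of the wide spread: with its score as a covariate the biological coefficient of variation was still 2.18 times that of the pituitary (2.04 to 2.44 when each mouse was left out, a spread added after the value was seen), down from 3.03 times. A spread too wide for 1.5-fold changes stays open: edgeR called 10.4% of such simulated changes and limma voom 11.9%, but DESeq2 called 38.8%, with 46 of its 186 calls unchanged genes, and it called 0 in the real libraries. By genes with an unadjusted p under 0.05, 99 of the 100 splits gave at least the real 89, the real one included (median of the others 377). With a real count of 0 calls, all 100 splits had to give at least as many calls, which tells nothing about chance. However, 1 other split gave 2774 calls, which points to a structure of the samples. In that split one side held the 5 libraries with the highest lymph node scores, and for 3 of the 27 lists, that one included, the 5 highest libraries made up one side.

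For the contrast between tissues the real count by edgeR was also 0 (427 at an unadjusted p under 0.05, against 526 by DESeq2, which called 1, and 538 by limma voom, which called 0). The 100 of 100 splits with at least as many calls thus tell nothing about chance. The highest other split gave 1222 calls, which points to a structure of the samples. By genes with an unadjusted p under 0.05, 78 of the 100 splits gave at least the real 427, the real one included (median of the others 649).

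Single libraries stood apart from the other 4 of their group in 13 of 188 groups of 5 checked, where chance gives about 1 in 20. The ratio given is the gap to the nearest library over the range of the group, above a critical value of 0.71. In the pituitary these were Tgfa in WT replicate 56 (15.4 CPM, ratio 0.862), Cldn7 (11.9 CPM, ratio 0.764) and Megf10 (36.2 CPM, ratio 0.846) in KO replicate 35, and the cell cycle score in KO replicate 50 (2.83, ratio 0.835). In iWAT KO replicate 50, Saa1 (152.6 CPM, ratio 0.924) and the blood marker score (8.69, ratio 0.805) were high and the lymph node score (1.23, ratio 0.812) was low. In the other iWAT libraries they were Klf14 in WT replicate 33 (3.003 CPM, ratio 0.758), BC022687 (1.402 CPM, ratio 0.895) and the inflammation score (2.66, ratio 0.866) in WT replicate 56, Ido2 (0.964 CPM, ratio 0.728) and the preadipocyte and fibroblast score (7.02, ratio 0.723) in KO replicate 32, and the score of other reported KLF14 targets in KO replicate 31 (4.38, ratio 0.830).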

How the results depend on the processing

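Surrogate variables, the 3 scores together in iWAT and the lists without each mouse in turn were chosen after seeing the data. Against 90 pituitary calls, DESeq2 gave 288, a threshold of 0.1 gave 192, 2 surrogate variables gave 221, age as a covariate 44 (38 of them among the 90), 21-week mice 5 (fewer samples), and 1 fit over all 20 libraries 1. Leaving out 1 mouse gave 50 to 112, with 55 without KO replicate 32, 50 without WT replicate 49 and 51 without WT replicate 56. Of 621 values of 27 named pituitary genes over 23 alternatives, 545 kept their call, 76 lost it and 0 reversed. iWAT gave 0 calls under every alternative run with edgeR, DESeq2 and limma voom (70 to 577 at an unadjusted p under 0.05). The contrast between tissues gave 1 call with DESeq2, 1 with age as a covariate and 0 under the other alternatives. With the mouse number as a block it gave 0 (333 at an unadjusted p under 0.05). Numbers were not taken to pair the libraries. Same-numbered libraries correlated at a median of 0.055 (1 of 10 above 0.1), and 4 of 10 correlated best with their own number. These values cannot decide whether a number stands for the same animal, because different tissues of an animal need not deviate alike. Lists past the threshold numbered 1 in the pituitary and 5 in iWAT, and 0 and 0 with an estimated correlation, 0 and 0 with fry, 3 and 5 with age as a covariate, and 0 to 4 and 1 to 11 without 1 mouse. Klf14 in iWAT reversed to -0.10 in 21-week mice, at a level near detection. In the fit over all 20 libraries the log2 differences of the 90 genes were a median of 0.999 times as large (0.9935 to 1.007). The median SE there was 0.194 against 0.084, so calls were lost by wider errors. With age as a covariate the differences were a median of 0.975 times as large (0.808 to 1.229), with a median SE of 0.093. Why calls were lost with age as a covariate was not tested, nor was the cause of the other changes. Depth limits low genes such as Klf14 in iWAT (1 to 49 counts).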

Other observations

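The tests of hormone genes, of acute-phase genes and of single chromosomes were chosen only after the result was seen. In iWAT KO replicate 32, Gh was at 91.5 CPM (1330 counts), Prl at 16.2 CPM and Pomc at 6.75 CPM, and in the other 9 iWAT libraries Gh was at most 0.955 CPM. The Gh level in that library is 0.0917% of the pituitary median. Prl was 17.7% of Gh there, and between 21.0% and 27.4% in the pituitary libraries.

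The iWAT library of KO replicate 50 was high in acute-phase and neutrophil genes besides Saa1. Saa3 was at 40.8 CPM, S100a8 at 40.5 CPM and S100a9 at 63.7 CPM, against at most 6.82, 1.96 and 2.82 CPM in the other iWAT libraries. These genes were chosen after their values were seen.

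Chromosome 6, which carries Klf14, held 10 of the 90 pituitary calls among 788 tested genes (Fisher's exact test, p = 0.0111, adjusted p = 0.233 over the chromosomes), so it did not pass.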
